A study of Mus musculus with 2 samples.

How the data were processed

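RNA abundance per gene was measured by RNA sequencing in mouse embryonic stem cells of the line R1E, which were labelled wild type. Embryonic stem cells are pluripotent cells taken from the early embryo and kept dividing in culture. Per the labels, the cells grew in serum medium with leukemia inhibitory factor (LIF), a cytokine that keeps mouse stem cells undifferentiated. The 2 libraries were an untreated one, labelled 0 h, and one from cells given 0.5 µM Adriamycin for 8 h. Adriamycin is doxorubicin, a topoisomerase II poison that leaves breaks in DNA. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit. How RNA was selected for the libraries is not given in the sources used here.

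The deposited values are raw read counts per gene, 1 table per library, not normalized. Per the file headers, featureCounts 2.0.3 counted paired-end reads over the exons of annotation release 105 of the mouse genome build GRCm39, keeping pairs with both ends aligned. The command in the header sets no strand option, so reads of overlapping genes on opposite strands were not told apart. It also has no option to count reads that map to several places or overlap several genes. It has no option to count pairs as 1 fragment, and in both tables a count of 2 was more frequent than a count of 1 (2067 against 1629 genes in the untreated library, 2266 against 1719 in the Adriamycin library), as separate counting of mates would give. The submitters' processing notes name Trim Galore 0.3.4, FastQC, HISAT2 2.0.4, featureCounts 1.6.0 and DESeq2 1.16.1, with the builds mm9 and mm10. The counter version and the build in the notes differ from those in the file headers. The exon positions in the tables are those the headers name, so positions are given here on GRCm39. The DESeq2 output of the authors was not analysed here.

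The tables hold 55414 gene identifiers, in the same order. Symbols came from the GENCODE M21 gene names, matched by Ensembl identifier, with 52081 identifiers matched and 3333 not. The unmatched ones held 0.0403% of the untreated reads and 0.0979% of the Adriamycin reads. M21 belongs to another build and gave only names, gene types and transcript sequences for GC content. All coordinates are from the deposited tables. No column of per-sample values was left unused.

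The total was 41820999 reads in the untreated library and 38561292 in the Adriamycin library. Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.951 and 1.05. CPM (read counts scaled to library size) and ratios were computed here from the deposited counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The log2 ratio of a gene is that of the Adriamycin over the untreated library, after a pseudocount of 0.5 read scaled to library size. It was computed for the 14871 genes with a mean of at least 1 CPM over both libraries, called measured here, and 40543 genes fell under that level.

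There is 1 library per condition and no replicate, so no test between conditions and no p-value was possible. Nothing in the labels tells whether the cultures were grown side by side, and any difference between the cultures or library preparations adds to that of the treatment. So does any effect of time in culture, since the untreated library is labelled 0 h and has no counterpart at 8 h. A gene was called higher or lower by a rule of size, a ratio of at least 2-fold. Each ratio has an exact 95% counting interval (conditional binomial, Clopper-Pearson), which covers counting error only. Mates counted separately and copies made by PCR are not independent molecules, so these intervals are too narrow. They were also computed on counts divided by 2, the number of reads in a pair. A count of 0 allows up to 3 reads, which is 0.0754 CPM in the untreated and 0.0740 CPM in the Adriamycin library. A fold against a count of 0 was taken against that floor and is written as a lower bound.

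Gene lists, 34 in all, the rule for named genes and the main alternatives were fixed before the data were examined. Each list with at least 5 measured members was described by its median log2 ratio, placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is called above or below the range of random lists past their 97.5 or 2.5 percentile. This describes the 2 libraries and is not a test of the treatment. The named genes are Trp53, Mdm2, Cdkn1a, Pou5f1, Sox2 and Nanog, the 10 higher and 10 lower measured genes whose counting interval lay farthest from no difference (predicted gene names left out), up to 4 such members of each list, and the 5 genes with the highest counts in each library. Bax, Gadd45a, Lefty1, Nodal, Psrc1, Fzd5, Fzd7, Axin2, Fn1 and Col1a2 were named after their values were seen, and so were the genes overlapping named ones. Some genes that the rule names are not reported here. The bands of expression were set on mean CPM after bands on untreated CPM had been seen, because those favour higher genes. Exons shared with other genes were found with bedtools 2.31.1 on the deposited coordinates. Genes with many near-identical copies lose reads in this kind of counting, and their values are uncertain.

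The calculation was tested on simulated counts for this comparison, drawn from the observed means and library sizes of 14864 genes, of which 200 were changed. With a true log2 ratio of 1.5, 100% of the changed genes were called, and with -1.5, 98%. With 3 and with -3, 100% were called. None of the 14664 unchanged genes was called, and 94.9% of their intervals held no difference. Of 200 random unchanged lists, 5.5% fell outside the 2.5 to 97.5 percentiles. The simulation holds counting error only, so it does not cover differences between cultures.

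Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, no filter on low counts, a mean of at least 5 CPM, a pseudocount of 5, calls from the interval bound, a threshold of 3-fold, thinning to equal totals, and leaving out mitochondrial and ribosomal protein genes. Calls from the interval bound of counts divided by 2 and protein-coding genes alone were added after seeing the data. Tests on the 2-cell-like genes, of reads shared between near-identical copies and of a general difference of scarce transcripts, were run first. The closing section weighs a segment of chromosome 19 in their place, chosen after the medians of 20 chromosomes had been scanned, and the 2-cell-like values are given in the report. A first criterion for a copy number of whole chromosomes was the share of 10 Mb windows on the same side of the median of all genes. It was met by 6 of 6 windows of chromosome 19 and 10 of 11 of X, and was replaced by tests on the segment after the window values had been seen. A first test of a lower share of stem cells, on the spread of the pluripotency genes, was replaced by one on the markers of other cell types, because it does not decide. The quartiles lay 1.01 apart, more than the 0.3 set for a shared shift, but random lists matched on expression were also spread by 0.48 to 1.08. For fibroblasts, the median of the list did not decide either, and its single markers were counted in its place. Neither the pooled markers of the other types nor this count decides. Figures were drawn with matplotlib 3.10.9.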

Results

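RNA-seq read counts were compared between untreated mouse embryonic stem cells of the line R1E and the same line given 0.5 µM Adriamycin (doxorubicin) for 8 h. The comparison asks how transcript levels of these cells differ with and without the drug. Each condition has 1 library and no replicate, so every statement below describes these 2 libraries, and a difference between the cultures cannot be separated from the treatment. The untreated library was labelled 0 h and there was no untreated library at 8 h. Time in culture can thus not be separated from the drug either. The untreated library held 41820999 reads and the Adriamycin library 38561292. At least 1 read fell on 25333 and 27096 genes, and the 10 genes with most reads took 4.98% and 4.83% of the totals. Log2 ratios are Adriamycin over untreated, and intervals in parentheses are 95% counting intervals, which cover counting error only.

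The genes farthest apart between the libraries included Wnt3, Slit1 and Krt5, with at most 15 reads in the untreated library. Wnt3, a secreted Wnt ligand, had 6 reads in the untreated library and 1097 in the Adriamycin library, a log2 ratio of 7.37 (6.36 to 8.94). Slit1, an axon guidance ligand, had 15 and 1600 reads (log2 ratio 6.66). Krt5, a keratin of basal epithelia, had 11 and 1199 reads (6.68), and the phospholipase gene Pla2g2f had 7 and 830 (6.76). Apol8 had 36 and 2851 reads (6.26). Against a floor of 3 untreated reads, Cbln2 with 0 and 365 reads was at least 119-fold higher and Zc3h12d with 0 and 210 reads at least 68.7-fold. The lower ends of their counting intervals, which include the error of the Adriamycin count, were lower, at log2 ratios of 6.59 and 5.79. With counts divided by 2 these ends were 5.59 and 4.78. Arhgef33 (3 and 928 reads, log2 ratio 8.03, 6.69 to 10.53), Klhl30 (2 and 486, 7.58, 6.04 to 10.95) and Ccdc81 (1 and 305, 7.65, 5.74 to 13.53) rested on very few untreated reads. On the other side, Pnp2 had 227 and 4 reads, 51.5-fold lower (log2 ratio -5.69, -7.74 to -4.48). Emp1, a membrane protein gene on chromosome 6 (135339543 to 135360171, GRCm39), was 10.8-fold lower with 3066 and 290 reads. Bmp4, a signalling ligand that works with LIF in stem cell culture, was 7.28-fold lower (2761 and 386 reads), and Fgf17 was 8.89-fold lower (1338 and 153 reads). Ankrd34a (13.8-fold), Vax2os (18.6-fold), Ldoc1 (11.5-fold), Lrtm2 (11.6-fold), Foxr2 (9.23-fold) and Mir124a-1hg (8.46-fold) completed the lower genes named by the rule.

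Of the 14871 measured genes, 2531 (17.0%) were at least 2-fold higher in the Adriamycin library, 1034 (6.95%) were at least 2-fold lower and 11306 were neither. The higher genes went further, with 1067 at 4-fold or more and 250 at 16-fold or more, against 105 and 2 of the lower genes. In the untreated library the higher genes had a median of 2.36 CPM and the lower genes 26.5 CPM, and in the Adriamycin library 10.3 and 9.62 CPM. Calling genes on the ratio itself produces part of that contrast. Among genes with a mean of 1 to 5 CPM, 31.8% were higher and 9.51% lower. Among genes with a mean of at least 100 CPM, 7.02% were higher and 8.89% lower. Protein-coding genes were 2288 of the higher and 836 of the lower genes. The counting interval of every called gene excluded no difference, also with counts divided by 2. At this depth the expression filter and the 2-fold rule leave little room for another outcome, so this is no check of the calls. Higher genes were 71.0% of those called with TMM scaling, 80.2% with total counts and 61.6% with upper-quartile factors.

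**Figure D1:**
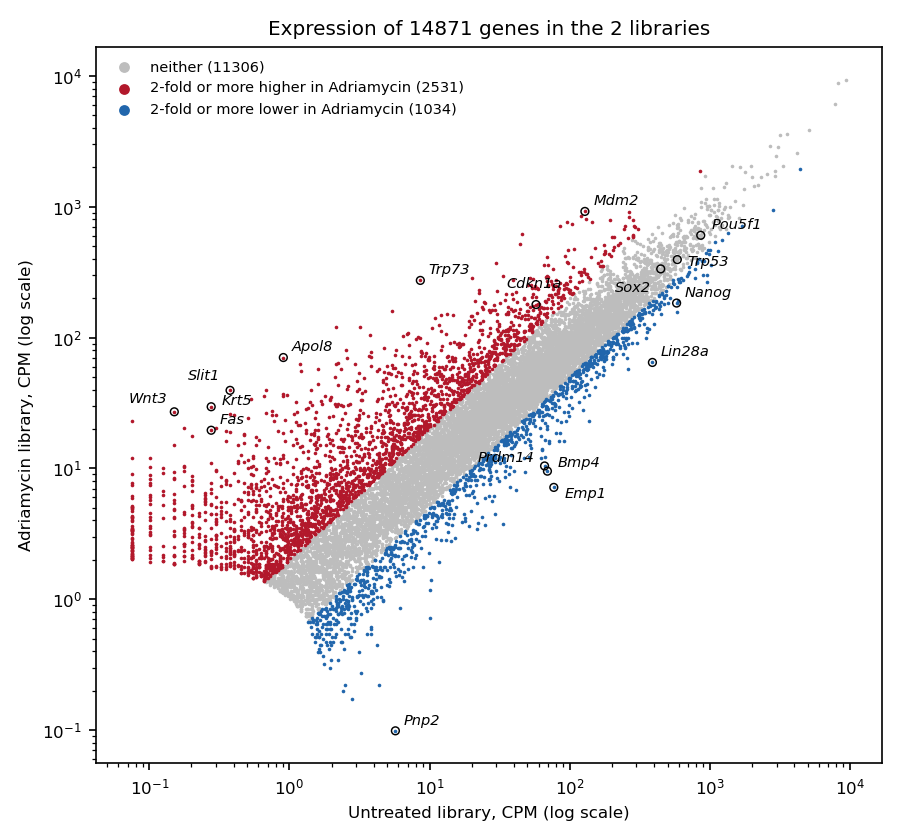
Each point is 1 of 14871 measured genes, at its CPM in the untreated library (horizontal) and in the Adriamycin library (vertical), both on log scales. Red marks the 2531 genes at least 2-fold higher, blue the 1034 at least 2-fold lower and grey the rest. Counts under 3 reads are drawn at the level of 3 reads.

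Target genes of p53, the transcription factor that responds to DNA damage, were higher as a group. Of 53 measured members, 36 were at least 2-fold higher and 0 were lower. The list's median log2 ratio was 1.55, above that of all 10000 random lists. Mdm2, the ubiquitin ligase that degrades p53 (ENSMUSG00000020184, chromosome 10, 117524780 to 117546663, GRCm39), was 7.16-fold higher, with 5110 and 37286 reads and a log2 ratio of 2.84 (2.80 to 2.88). Cdkn1a, the CDK inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29309950 to 29319701), was 3.10-fold higher with 2289 and 7240 reads (log2 ratio 1.63, 1.57 to 1.70). The death receptor gene Fas (chromosome 19, 34268066 to 34305172) had 11 and 793 reads, a log2 ratio of 6.08 (5.30 to 7.15). Fas lies in a part of chromosome 19 whose genes were higher as a group, with a median log2 ratio of 0.83. Ptprv was 14.2-fold, Plk2 12.4-fold and Dcxr 10.3-fold higher. Some members differed little, such as Bax with a log2 ratio of 0.33 and Gadd45a with -0.10. The transcript of p53 itself, Trp53 (ENSMUSG00000059552, chromosome 11, 69471185 to 69482699), had 23334 and 15982 reads, a log2 ratio of -0.57 (-0.60 to -0.54).

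Among 21 p53 family members and regulators, 4 were higher and 1 was lower, and the median of -0.06 lay above 8224 of the 10000 random lists. That median was above 0 with total counts, and the mean was 0.29. The 4 higher ones were Mdm2, Trp73, Ppm1d and Wrap53. Trp73, a relative of p53, was 31.7-fold higher with 342 and 11074 reads (log2 ratio 4.99, 4.83 to 5.15). Ppm1d, a phosphatase that counteracts p53, was 3.26-fold higher, and Wrap53, which lies head to head with Trp53, 2.60-fold higher. Pro-apoptotic genes had 7 higher and 1 lower of 28, with a median of 0.60 above 9998 random lists. They share 10 measured members with the p53 targets, among them Fas, Perp (8.96-fold higher), Apaf1 (5.47-fold) and Pidd1 (4.80-fold). The 18 others had a median of -0.10, with 1 higher. Anti-apoptotic genes had 0 higher and 1 lower of 13, with a median of -0.50 above 334 random lists, inside the range. In that list Mcl1 had a log2 ratio of 0.59. The 1 lower member was Bnip3 (2.31-fold), whose product is better known for promoting cell death, so its place on the list is doubtful.

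DNA repair genes stood within the range of random lists, with 2 higher and 0 lower of 57 and a median of -0.14 (4583 random lists below), which was 0.01 with total counts. The higher ones were Ercc5, an excision repair nuclease gene that is also on the p53 target list (log2 ratio 2.49, 1378 and 7872 reads), and Rad51d, a recombination gene (log2 ratio 1.59, 813 and 2490 reads). Topoisomerases and drug transporters had 2 higher and 0 lower of 14, with a median of -0.16 (6239 random lists below) and a mean of 0.11. Abcb1b, a P-glycoprotein gene whose product exports doxorubicin, was 5.31-fold higher with 1660 and 8995 reads. Top1mt was 2.54-fold higher. Top2a, a topoisomerase II gene, had 47116 and 27192 reads, a log2 ratio of -0.82 (-0.84 to -0.80).

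**Figure D2:**
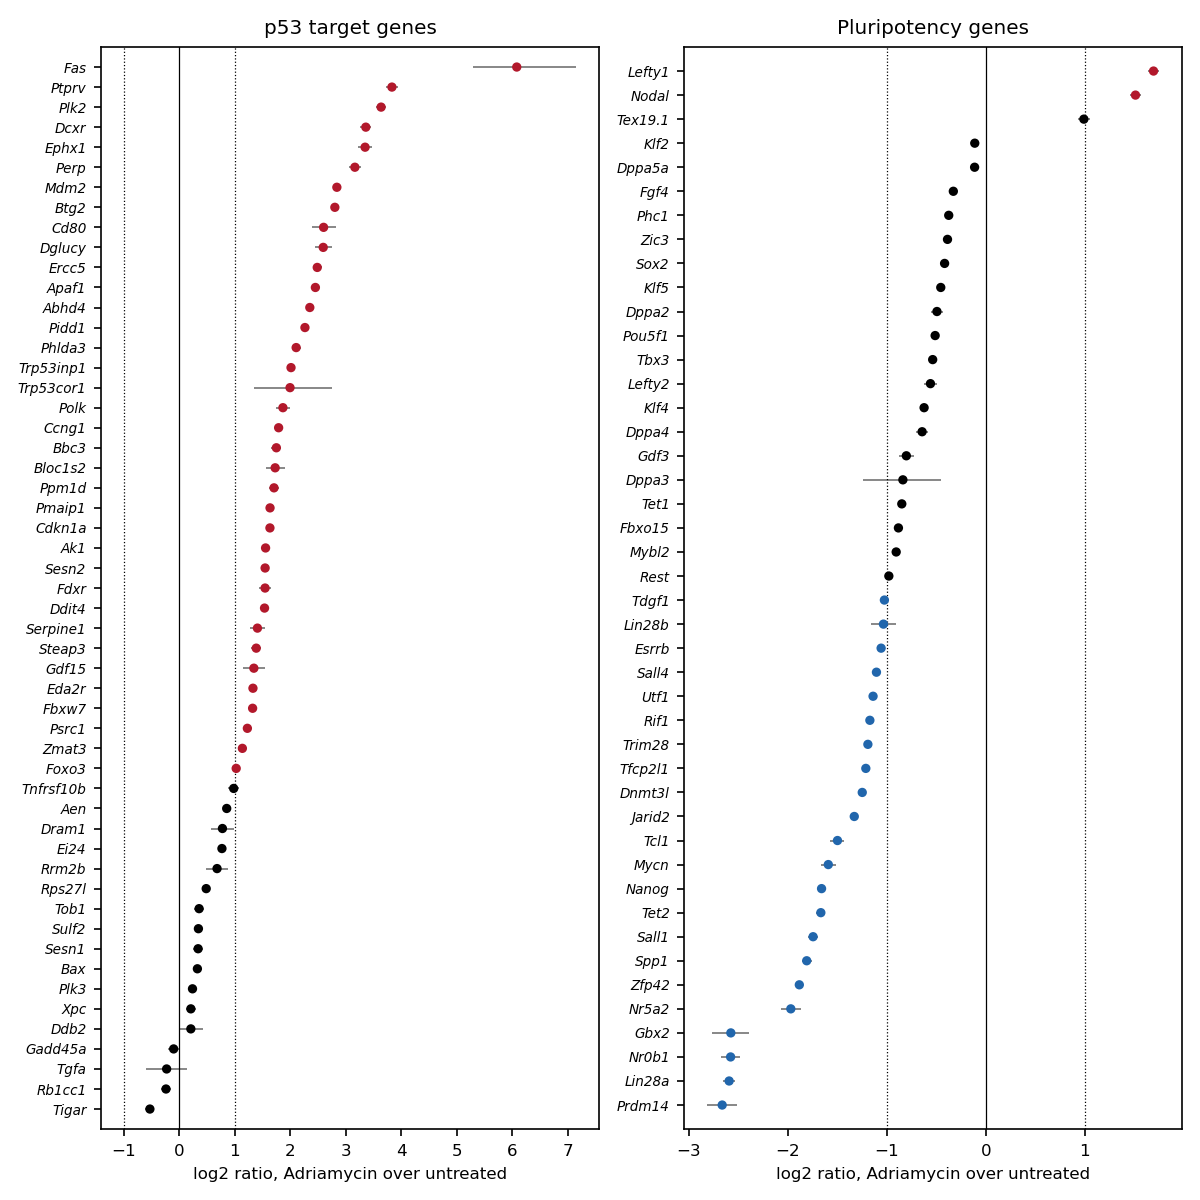
Each row is a measured gene of the p53 target list (left, 53 genes) or the pluripotency list (right, 44 genes), at its log2 ratio of Adriamycin over untreated, with its 95% counting interval as a bar. Dotted lines mark 2-fold. Red genes (36 left, 2 right) are at least 2-fold higher and blue genes (0 left, 22 right) at least 2-fold lower. The panels have different horizontal scales.

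Pluripotency genes were lower as a group but by unequal amounts. Of 44 measured members 22 were at least 2-fold lower and 2 were higher, and the median of -1.003 lay below all 10000 random lists. Nanog, a core pluripotency factor (ENSMUSG00000012396, chromosome 6, 122684448 to 122691592), was 3.16-fold lower with 23059 and 7436 reads (log2 ratio -1.66, -1.70 to -1.62). The core factors Pou5f1 (ENSMUSG00000024406, chromosome 17, 35816915 to 35821669) and Sox2 (ENSMUSG00000074637, chromosome 3, 34704554 to 34706610) did not reach 2-fold. Pou5f1 had 34285 and 24502 reads (-0.51, -0.54 to -0.49) and Sox2 17762 and 13563 (-0.42, -0.45 to -0.38). Prdm14 was 6.34-fold, Lin28a 6.04-fold, Nr0b1 5.98-fold and Gbx2 5.97-fold lower. Exons of Gbx2 overlap those of D130058E05Rik on the opposite strand, and Gbx2 is also on the list of LIF and STAT3 response genes. The 2 higher members were Lefty1 and Nodal, which act in the Nodal pathway, at log2 ratios of 1.69 and 1.51. Fibroblast markers, listed for feeder cells, had a median of 0.81, with members that moved apart.

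Genes of the formative and primed states, which follow naive pluripotency, were lower too. Of 19 measured, 11 were lower and 1 was higher, with a median of -1.19 below all random lists. Zic2 was 6.73-fold, Zic5 5.82-fold, Foxd3 5.16-fold and Lef1 4.14-fold lower. Response genes of LIF and STAT3 had 2 higher and 6 lower of 14, with a median of -0.82 above 3 random lists. Bcl3 was 5.24-fold lower and Il6st, the shared receptor subunit gp130, 3.10-fold lower, while Lif itself was 6.07-fold higher (117 and 726 reads). DNA methylation and Polycomb genes had 0 higher and 9 lower of 34, with a median of -0.65 above 1 random list. Tet2 was 3.18-fold, Jarid2 2.51-fold and Dnmt3a 2.41-fold lower. Dnmt3l was 2.38-fold lower, and its exons overlap those of Aire on the opposite strand. Tet2, Jarid2 and Dnmt3l are also on the pluripotency list. Dnmt3a and Dnmt3b (2.06-fold lower) are also on the formative and primed list. The fall of this list is thus not independent of those 2.

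Genes of G2 and M phase were lower as a group, with 13 lower and 2 higher of 57 and a median of -0.70 below all random lists. Plk1, a mitotic kinase, was 3.66-fold lower with 10229 and 2851 reads, G2e3 3.10-fold and Kif23, a kinesin of cell division, 2.73-fold lower. The 2 higher members were Ckap2 (2.60-fold) and Psrc1, which is also on the p53 target list. S phase genes lay inside the range of random lists, with 0 higher and 2 lower of 46 and a median of -0.31 (1986 random lists below). Ccne1, the cyclin E1 gene, was 3.20-fold and E2f8 2.13-fold lower. Cyclins, CDKs and CDK inhibitors had 6 higher and 7 lower of 28, with a median of -0.47 above 47 random lists. The CDK inhibitor gene Cdkn2b was 11.1-fold higher (73 and 831 reads), and Cdk6 was 4.08-fold lower. The retinoblastoma family genes Rbl2 and Rb1, kept on the same list, were 6.61-fold and 4.99-fold higher. Both have exons that overlap genes on the opposite strand, Aktip for Rbl2, and Rcbtb2 and Lpar6 for Rb1.

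Genes of the state that resembles the 2-cell embryo were higher, with 11 higher and 0 lower of 27 and a median of 0.84 above 9996 random lists. Zfp750 was 11.4-fold higher (253 and 2943 reads) and Tmem92 2.21-fold. Duxf3, a Dux family gene, was 5.70-fold higher on 33 and 194 reads, and Usp17le 2.30-fold higher. Many members have near-identical copies, which makes their values uncertain. By the start of their symbols, 9 members stood alone in the list, with a median of 1.05, and the 18 others had 0.60. This grouping goes by name only, and the 9 include Duxf3. It thus does not set apart genes without near-identical copies. The 6 Zscan4 genes had log2 ratios from 0.51 to 0.74.

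The Wnt list had 12 higher and 3 lower of 25, with a median of 0.74 above 9970 random lists. Its higher members were mostly ligands, such as Wnt9a (16.3-fold, 104 and 1741 reads), Wnt3a (12.2-fold, 64 and 800 reads) and Wnt8b (30.9-fold, 12 and 393 reads). The lower ones were Lef1, a nuclear effector of the pathway, and the receptors Fzd5 (log2 ratio -1.06) and Fzd7 (4327 and 2199 reads). Wnt target Axin2 had a log2 ratio of -0.93.

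Fibroblast markers had 5 higher and 0 lower of 12, with a median of 0.81 above 9865 random lists. Fbln2 was 8.63-fold higher (247 and 2177 reads), Col1a1 5.92-fold (214 and 1295 reads), Bgn 3.16-fold and Col6a1 14.1-fold on 7 and 107 reads. Other members differed less or were lower, such as Col1a2 with 59 and 62 reads (log2 ratio 0.04) and Fn1 with a log2 ratio of -0.56. Markers of other lineages lay inside the range of random lists. Endoderm markers had 2 higher and 0 lower of 16 (median 0.03, 6548 random lists below, and below 0 with upper-quartile factors), with Hnf4a 2.45-fold and Cxcr4 2.63-fold higher. Mesoderm markers had 3 higher and 3 lower of 12 (median -0.06, 1558 random lists below, above 0 with total counts, and a mean of 0.13). Among them Mesp2 was 10.1-fold and Mesp1 15.0-fold higher, and Eomes 5.20-fold lower. Neuroectoderm markers had 1 higher and 2 lower of 8 (median -0.42, 388 random lists below), with Neurod1 6.85-fold higher, Pax6 6.06-fold and Sox11 2.98-fold lower. Trophoblast markers had 3 higher and 2 lower of 15 (median 0.28, 7456 random lists below). Krt7 was 9.85-fold and Cdh3 2.73-fold higher, and Tead4 2.65-fold lower. Of blood markers 3 were measured, too few for a percentile, with a median of 0.29. Cd3e was 2.01-fold higher on 47 and 97 reads, and Cd68 had a log2 ratio of 0.12, which was below 0 with upper-quartile factors.

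Immediate early genes had 8 higher and 1 lower of 26, with a median of 0.38 above 9822 random lists. Fos was 6.02-fold higher (206 and 1267 reads), Dusp2 15.1-fold higher (44 and 685 reads) and Ier3 4.04-fold lower. Fosl1 was 51.9-fold higher on 6 and 343 reads, and its exons overlap those of Ccdc85b on the opposite strand. Interferon-stimulated genes had 3 higher and 5 lower of 13, with a median of -0.60 above 23 random lists and a mean of 0.03. Ddx58, the RNA sensor RIG-I, was 5.13-fold lower (1900 and 377 reads). Zbp1, a nucleic acid sensor, was 12.1-fold higher (47 and 587 reads). Cxcl10 was 24.8-fold higher on 10 and 265 reads, and its exons overlap those of Art3 on the opposite strand, which had 4 and 337 reads. NF-kB target genes had 2 higher and 1 lower of 13 (median 0.02, 5621 random lists below, and below 0 with upper-quartile factors), with Cd40 4.62-fold and Traf1 2.08-fold higher.

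Heat shock and chaperone genes had 3 higher and 2 lower of 22, with a median of -0.57 above 40 random lists. Hsp90b1 and Hsph1 were 2.07-fold and 2.09-fold lower, and Hspa2 was 2.37-fold higher. Hspa1a was 5.85-fold higher on 77 and 462 reads, an uncertain value because Hspa1b is nearly identical. Integrated stress response genes had 3 higher and 6 lower of 23 (median -0.41, 323 random lists below, inside the range). Chac1 was 3.19-fold lower, while Sesn2 (2.92-fold) and Ddit4 (2.90-fold), both also p53 targets, were higher. Cebpb was 7.26-fold higher on 54 and 403 reads, and its exons overlap those of Tmem189. NRF2 and oxidative stress genes had 1 higher and 1 lower of 23 (median -0.08, 7854 random lists below, and above 0 with total counts). These were Fth1, a ferritin gene, 2.76-fold higher, and the cystine transporter gene Slc7a11, 2.27-fold lower.

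Cholesterol synthesis genes had 0 higher and 4 lower of 23, with a median of -0.52 above 50 random lists. Sqle was 2.10-fold, Ebp 2.28-fold and Fdps 2.87-fold lower. Fdps has pseudogene copies and its count is uncertain. Glycolysis genes had 1 higher and 3 lower of 22 (median -0.46, 796 random lists below, inside the range). The glucose transporter gene Slc2a3 was 2.97-fold lower (111934 and 38418 reads), Hk2 3.22-fold and Pfkp 2.29-fold lower, and Pfkfb4 was 4.96-fold higher. Exons of Pfkp overlap those of Pitrm1 on the opposite strand. Long non-coding RNA genes had 2 higher and 5 lower of 19 (median -0.25, 895 random lists below). Neat1 was 2.24-fold higher, Trp53cor1 3.99-fold higher on 23 and 95 reads with exons overlapping AC167363.1, Snhg5 2.55-fold lower and Mir17hg 2.28-fold lower.

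Genes often used as references had 0 higher and 1 lower of 14 (median -0.21, 5355 random lists below), the lower one being Tfrc, the transferrin receptor gene (2.72-fold). Actb had a log2 ratio of -0.70. Replication-dependent histone genes had 0 higher and 1 lower of 11 (median -0.41, 251 random lists below), with Hist1h2af 5.19-fold lower on 109 and 21 reads. Ribosomal protein genes had 0 higher and 2 lower of 83 (median -0.12, 8961 random lists below, and above 0 with total counts). Rpl17 was 2.27-fold lower, and many genes of this list share sequence with pseudogenes. All 37 mitochondrial genes were listed at 0 reads in both libraries, so nothing can be said of them. Among the genes with the highest counts, Eef1a1 had 374896 and 379668 reads (log2 ratio -0.01), Eef2 328592 and 355185 (0.08) and Rack1 141051 and 146744 (0.03), and the sign of each depended on the scaling. Hsp90ab1 had a log2 ratio of -0.35 and Pkm, whose exons overlap those of Gm49759, -0.41. Trim28, a pluripotency list member among the highest counts, was 2.29-fold lower (175934 and 78487 reads).

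**Figure D3:**
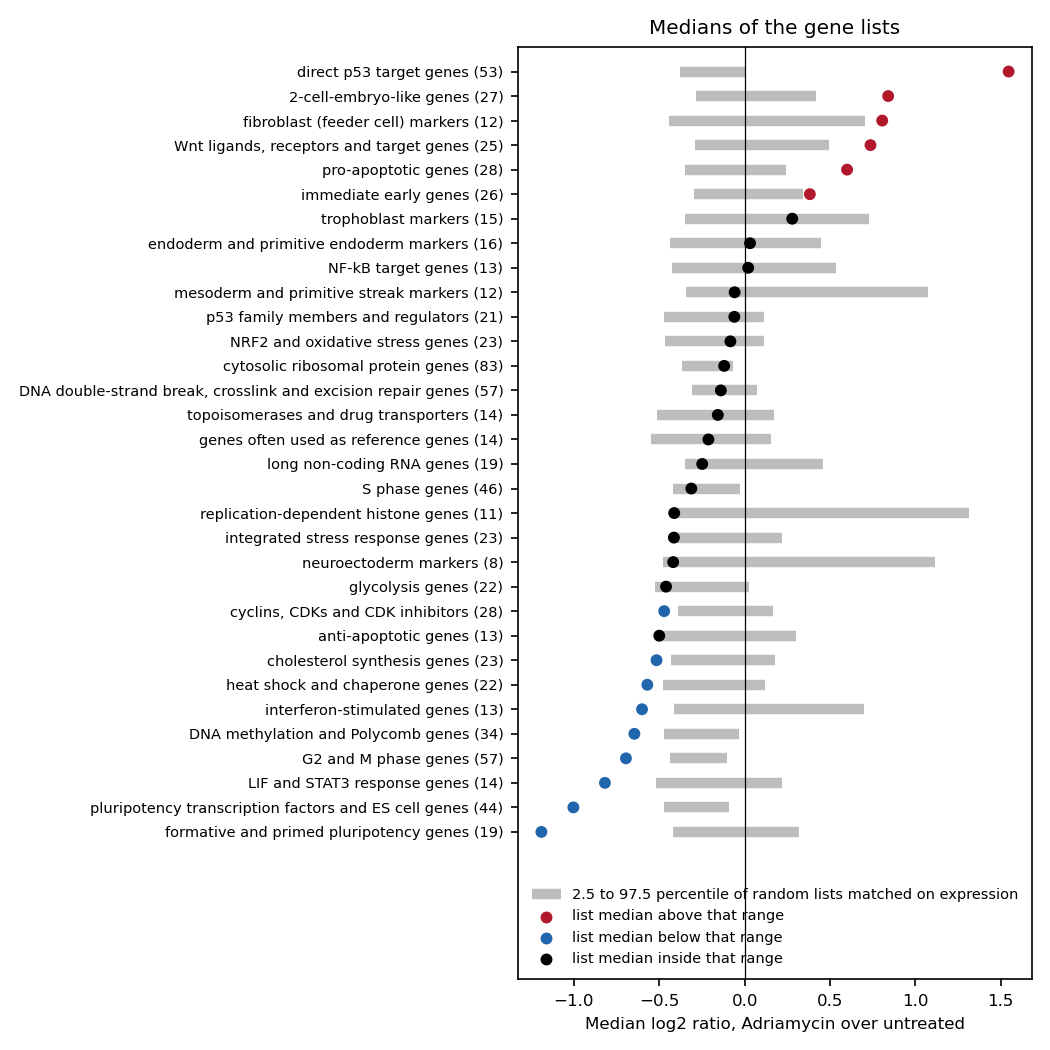
Each row is a gene list with its number of measured members in parentheses, and each dot is the list's median log2 ratio of Adriamycin over untreated. Grey bars span the central 95% of the medians of 10000 random lists matched on expression. Of 32 lists, 6 lie above (red), 9 below (blue) and 17 inside (black) their bar.

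By position, medians were computed for 221 windows of 10 Mb with at least 20 measured genes, a scan chosen after the values were seen. The 3 highest were adjacent, on chromosome 19 from 10 to 40 Mb (GRCm39), with medians of 0.76, 0.99 and 0.76. The highest window of any other chromosome was at 0.63, on chromosome 7 from 60 to 70 Mb. Of the 138 measured genes in that segment of chromosome 19, 59 were higher and 2 lower, and 122 (88.4%) had a log2 ratio above 0, against 48.4% of all measured genes. On either side, the 198 measured genes from 0 to 10 Mb had a median of 0.02, and the 109 from 40 to 50 Mb a median of 0.33, with 22 higher and 6 lower. The 34 from 50 to 60 Mb had a median of 0.04, with 5 higher and 2 lower.

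**Figure D4:**
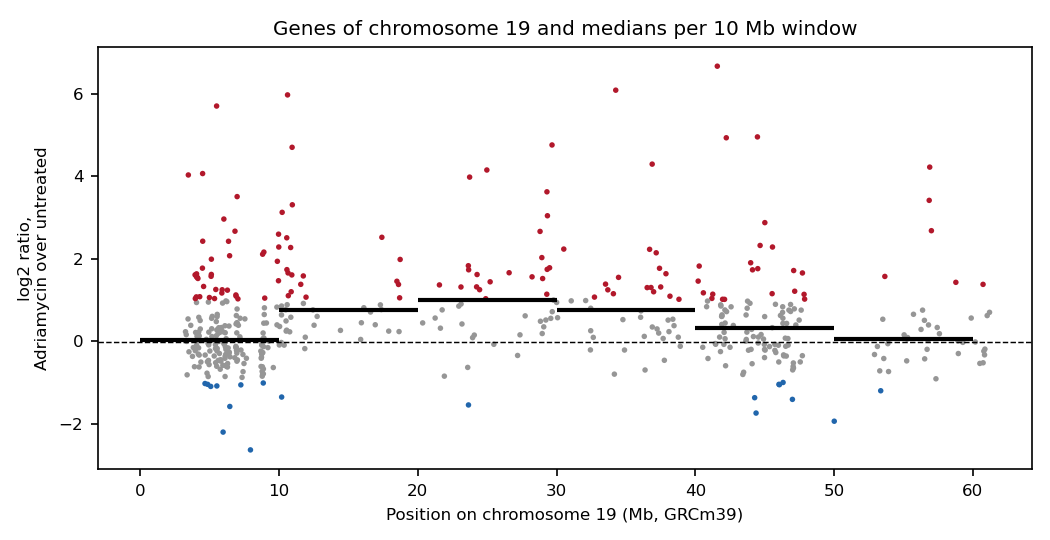
Each point is a measured gene of chromosome 19 at the position of its start (Mb, GRCm39) and its log2 ratio of Adriamycin over untreated. Red and blue mark genes at least 2-fold higher and lower. Black bars are medians per 10 Mb window, which reach 0.76, 0.99 and 0.76 between 10 and 40 Mb, and the dashed line is the median of all measured genes (-0.03).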

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

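The calls from the interval bound of counts divided by 2 and those over protein-coding genes alone were tried only after the data were seen. Without a filter on low counts, 8514 genes were higher and 4292 lower, since many genes with few reads then enter. With a mean of at least 5 CPM, 1417 of 11371 genes were higher. The genes with a mean of 1 to 5 CPM, of which 31.8% were higher, then dropped out. At 3-fold, 1466 were higher, 258 lower and 11 pluripotency genes lower, and with the interval bound past 2-fold, 662 were lower, or 547 with counts divided by 2. All other counts of called genes, p53 targets and pluripotency genes stayed within 1.5 times. Higher p53 targets numbered 24 to 37 and lower pluripotency genes 11 to 25 over all alternatives. Total counts moved the median of all genes by 0.15 and upper-quartile factors by -0.12, so list medians near 0 depend on the scaling. With total counts the medians of the p53 regulator, mesoderm, DNA repair, NRF2 and ribosomal protein lists changed sign, and with upper-quartile factors those of the endoderm and NF-kB lists. These are 7 of 263 list values. Of 1244 values of named genes, 4 changed sign, none of them of a called gene, and 154 left their counting interval. Of all 219 list and gene values that did, 104 came with total counts and 98 with upper-quartile factors, which shift every gene. The cause of the other 17 was not tested. No paired analysis was possible because each condition has 1 library. Depth limits genes near 1 CPM, where a fold rests on few reads, and replicates are lacking for every value.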

Other observations

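The scans of gene families and of chromosome positions (20 chromosomes, then 221 windows), the bounds of the chromosome 19 segment, all tests on it, and the tests on abundant transcripts and on stem cells replaced by other types, were chosen only after the results were seen. Among 160 groups of genes that share the start of their symbol, with 2000 random lists each, 14 lay above and 7 below the range of random lists, where chance would give about 4 on each side. Wnt genes led, with 8 of 12 higher (median log2 ratio 2.40), overlapping the Wnt list. Voltage-gated calcium channel subunits (Cacna) had 6 of 11 higher (median 1.75), cytochrome P450 genes (Cyp) 14 of 23 higher and 3 lower (1.77), keratins (Krt) 9 of 15 higher and 1 lower (1.62), and collagens (Col) 17 of 31 higher (1.45). Tubulin tyrosine ligase-like genes (Ttll) had 5 of 10 higher (1.35). Mapk genes lay below the range, with 2 of 17 lower and 0 higher (median -0.67). Of the chromosomes, X had the lowest median, -0.34, with 39 higher and 62 lower of 496 genes. Of its 11 windows of 10 Mb, 10 lay below the median of all genes.

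More genes were at least 2-fold higher than lower. Background reads along the genome do not account for it: 1519 genes of olfactory, vomeronasal, trace amine and defensin families were 1.71-fold higher (1.58 to 1.84), but their gain per kb of exon was 0.168% of the median gain of the higher genes. Transcription running on from a gene upstream, as the main cause, would place most higher genes behind expressed neighbours. But 20.98% of them had an expressed gene on the same strand ending within 10 kb upstream, 3.67 percentage points more than other genes of like expression. Neighbours on the opposite strand, whose reads the counting does not tell apart, were left out. A smaller part for such transcription stays open. The choice among the scalings tried is not the whole cause either. Higher genes were 61.6% of those called under the scaling least favourable to them (60.03 to 63.2, exact binomial interval). Scaling as the cause needed 50% or less, though the lower bound barely passed the 60% set beforehand. All these scalings use the read counts alone, so levels are relative, and a difference in total RNA per cell stays open. A response to Adriamycin and a difference between the cultures both stay open, since no replicate cultures were available to test them.

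Pluripotency genes were lower as a group, with a median of -1.003. A general fall of abundant transcripts does not reach it, because the lower end of the central 95% of random lists matched on expression was -0.47, nor does one of genes with a long span (-0.26 for lists matched on span). As the whole cause, stem cells replaced by other types would raise marker genes of those types. The markers were compared with the size of the pluripotency median. That size does not set how far a marker would rise, which depends on its level in both cell types. The 53 markers of endoderm, mesoderm, neuroectoderm, trophoblast and blood together had a median of 0.0884 (bootstrap interval -0.16 to 0.28). Replacement by only 1 of these types would raise a part of them and could leave that median little raised, so it does not decide. The single lists had medians of 0.03, -0.06, -0.42, 0.28 and 0.29, in that order. Each held at least 1 member that was 2-fold or more higher. Fibroblasts in place of the stem cells would bring all their abundant transcripts, but their markers do not decide either. The list's median was 0.81 (bootstrap interval 0.14 to 2.11). Of the 12 markers, 4 had an interval with counts divided by 2 that lay under the size of the pluripotency median (at least 9.92% by the exact interval). Col1a2 was among them at 1.53 CPM with Adriamycin, and so was Fn1, already at 1152 CPM in the untreated library. This count was set after values were seen, and the markers are no random sample. Replacement of stem cells by 1 of the other types or by fibroblasts stays open. So do a response to Adriamycin and another difference between the cultures, both untested.

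Genes on chromosome 19 from 10 to 40 Mb were higher as a group, with a median of 0.83 and a lower quartile of 0.27. Random lists from other chromosomes matched on GC content stayed under that median (upper end of their central 95% 0.0439), as did those matched on expression level (0.172). The lower quartile also exceeded that end for the lower quartiles of random lists (-0.29). The segment was chosen for high window medians, so a median above those of random lists was partly set by that choice. A few strongly higher genes could not give such medians, so the lower quartile is no separate test of such genes. A different copy number of the whole chromosome is argued against by its first 10 Mb, shifted by 0.0454 (bootstrap interval -0.07 to 0.20) from all genes, against 0.86 for the segment. But the genes from 40 to 50 Mb had a median of 0.33 and those from 50 to 60 Mb 0.04, so the end of the segment is not sharp. The shifts of the 69 less and 69 more expressed genes, from genes of like expression, were 0.847 and 0.855, a difference of -0.0076 (-0.52 to 0.34), too wide an interval to settle whether genes at every level were shifted alike. A different copy number of this segment is a candidate explanation, either as a gain in the treated culture or as a loss in the untreated one. Neither can be told apart from a regional response to the drug, since each condition has 1 culture.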
